A study of Drosophila melanogaster with 6 samples.

How the data were processed

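RNA was sequenced from the anterior midgut, the front part of the absorptive fly intestine, of Drosophila melanogaster given either sucrose or the bacterium Erwinia carotovora carotovora 15 (Ecc15) for 2, 4 or 16 h. Each of the 6 combinations of treatment and time had 1 library, so there were no replicates within a group. Per the labels' protocols, total RNA was isolated with a column kit, poly(A) RNA was selected, and libraries were made with an Illumina TruSeq kit. Whether a library pooled several animals is not given in the sources used here.

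Per the submitters' processing notes, the tools were cutadapt 1.6, TopHat2 2.0.7, Bowtie (no version) and Cufflinks 2.0.2. The genome build, the annotation, the handling of strand and the normalization are not given in the sources used here. The authors' deposited table holds 1 value per gene and library, which was read here as log2. That reading is an inference: the values run from 0 to 15.4, and 2 to the power of the value, minus 1, sums to 940047 in 4 libraries, 940044 in the 2 h sucrose library and 938535 in the 4 h infected library, as FPKM values could. Read as natural logarithms the sum would be 2.78e+07. The deposited log2 values were therefore treated as log2(FPKM + 1), and levels below are called FPKM-scale values. Sorted by size, 91.9% of ranks held a value within 0.0001 of the median library in all 6 libraries, the pattern that quantile normalization gives. Such a step forces every library to the same distribution, so a global shift of expression after infection could not be seen. The table holds no read counts, so the sequencing depth of each library is unknown, no counting interval can be given, and values near 0 have an unknown precision. The number of genes listed at the lowest value of a library was 2157, 1429 and 1147 for sucrose at 2, 4 and 16 h, and 1580, 1161 and 917 for Ecc15. A value of 0 can be a failed estimate, so such a gene is described as listed at 0, and no fold is given against it within a pair of the same time. Averages, other references and differences between times can still draw on such values and are then uncertain.

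The table had 14239 entries. The 22 without a gene identifier and the 383 that carried 178 repeated identifiers were left out, and 13834 were kept. Of these, 13670 identifiers matched a gene symbol in the reference table. Coordinates are those of the table, counted from 1. Their build is not given in the sources used here, and the median start differed from the annotation at hand by 0 on 2L, 4.11e+06 on 2R, 6898 on 3L, 4.17e+06 on 3R, -20629.5 on 4 and 105967 on X, so no exon or UTR was assigned. Genes with an FPKM-scale value of at least 1 in at least 1 library were analysed, which gave 9183 genes, 8802 of them protein-coding and 381 other. The design written before the data were examined assumed FPKM values; since the table holds log2 values, the planned log2 ratio with a pseudocount of 1 is the difference of the deposited values. It understates the change of weakly expressed genes.

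With 1 library per group no test was possible at a single time, so genes at least 2-fold higher or lower than the sucrose library of the same time were counted, beside the same count between sucrose libraries. The sustained response is the set of genes past 2-fold in the same direction at all 3 times. The number expected for independent lists is given beside it, and the 3 differences share no library. The one replicated test was limma 3.58.1 with an intensity trend on all 6 libraries, with terms for treatment and time and 2 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05. Its residual holds library noise and any change of the effect over time. Only genes passing that test are said to have risen or fallen. In simulated data of 9183 genes with 200 changed, it recovered 31% of genes changed 2-fold and 63% of those changed 4-fold, with 5 false calls of 99. The changed genes were drawn from the more strongly expressed ones and shifted equally at all 3 times, with noise independent between genes. Differences between libraries that many genes share were not simulated, so these shares may not hold for the real data. The 6 libraries are separate samples by their labels, and nothing says that they came from separate cohorts of flies, so these p-values measure the spread between these libraries.

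Before the data were examined, 28 pathway lists and 13 marker lists of tissues that a dissection could carry along were fixed. They held 806 entries, of which 20 were not matched to the table, and 34 identifiers stood in more than 1 list. For each list the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and lists outside the central 95% are reported as high or low. In simulated data, 7 of 100 lists without an effect fell outside the central 95%, and 98 of 100 lists of 20 genes shifted by 1 log2 unit lay above it. The simulated genes varied independently, so these shares do not cover lists whose members move together. Between sucrose libraries the largest median difference of a list, in either direction, ran from 0.06 (enterocyte) to 1.63 (ovary and eggshell). A percentile describes these libraries and is not a p-value. Genes were named by a rule fixed in advance: at each time the 10 largest differences in each direction among genes with an FPKM-scale value of at least 5 in the pair, up to 4 members per list with the largest absolute difference, 14 genes of prior interest, the 10 sustained genes per direction with the largest smallest difference, the 10 per direction with the smallest limma p, and the 5 per direction with the largest difference between 16 and 2 h in each treatment. Since small RNA genes took most of the places at single times, the 10 largest protein-coding differences were added after seeing the data. List members that passed limma are also named, a choice made after their values were seen. A list of 21 photoreceptor genes was written after the 4 h sucrose library had been seen.

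Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5, median-of-ratios scaling, rescaling to a constant sum, 1.5-fold and 3-fold rules, other sucrose references, limma without trend or without time, and leaving out each time. Others, added after seeing the data, were protein-coding genes alone, the mean of the sucrose libraries of the other times, 16 h against 4 h and leaving out each time in the sustained response. The mean of the sucrose libraries of the other times mixes infection with time, so it is a check on the matched sucrose library and not a better control. Reads of near-identical genes (the GstD cluster, Hsp70Aa and Hsp70Ab, CecA1 and CecA2, PGRP-SC1a and PGRP-SC1b, Cyp12d1-p and Cyp12d1-d, the trypsin cluster), of overlapping genes and of antisense partners can be split in ways that are unknown here, so single members of these families are uncertain. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.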

Results

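Poly(A) RNA of the Drosophila anterior midgut was measured in 6 libraries, 1 for each of sucrose and Ecc15 at 2, 4 and 16 h. Ecc15 is a bacterium that infects the fly gut when swallowed, and sucrose feeding served as the control. The study's title places the work in the metabolic side of gut immunity that depends on DUOX, the enzyme that makes microbicidal reactive oxygen species. The depth of the libraries is unknown, because the table holds log2 expression values and no counts. Across all genes, Spearman correlations between libraries ran from 0.929 to 0.957. With 1 library per group, the differences at a single time have no replicate check.

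The question at 2 h was how the gut's transcripts differ early after infection. Genes of antibacterial defence and cytokine signalling were higher in the infected library. DptA, which encodes an antibacterial diptericin, was 16.8-fold higher, pirk, a feedback inhibitor of the Imd immune pathway, 7.17-fold, and upd3, a cytokine that activates JAK-STAT signalling, 12.7-fold. Cytochrome P450 genes and genes of fat metabolism were lower, among them whd, the mitochondrial carnitine palmitoyltransferase, at -1.86 log2, and ACC, acetyl-CoA carboxylase, at -1.37. In total, 573 genes were at least 2-fold higher and 499 lower of 9183. Between sucrose libraries the counts were 297 and 153 for 4 h against 2 h, 228 and 287 for 16 h against 2 h, and 142 and 349 for 16 h against 4 h. Protein-coding genes made up 489 and 468 of the infection counts, and 30 of 63 rRNA genes were higher and 0 lower.

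Of 16 antimicrobial peptide genes, 10 were at least 2-fold higher at 2 h and 0 lower, with a list median of 1.21. AttD stood at 3.81 and CecA2 at 3.54, while CecA1 was listed at the lowest value in the 2 h sucrose library and at 5.67 after infection. Among 14 genes of peptidoglycan recognition and Imd feedback, 4 were higher: PGRP-SD by 3.51, pirk by 2.84, PGRP-LF by 2.65 and the amidase PGRP-LB by 2.13. Of 9 JAK-STAT genes 4 were higher, including Socs36E, a target and inhibitor of the pathway, by 2.94, and the list median was 0.77. JNK targets Ets21C and Gadd45 were higher by 3.78 and 3.10, with a list median of 0.18 inside the random range. Heat shock genes had a median of 0.56, led by Hsp23 at 2.24. Glutathione and redox genes had a median of 0.25, led by GstD8 at 2.82. The relish factor Rel of the Imd cascade was higher by 1.71, but that list had a median of -0.13, within random lists. Duox stood 1.44 higher and mol, its maturation factor, 0.63 higher, both at low levels (0.45 and 1.89 log2 for Duox in the 2 libraries). The ovary and eggshell list was higher in the same library, with a median of 2.13.

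On the lower side at 2 h, 15 of 37 cytochrome P450 genes were at least 2-fold lower and 2 higher, with a median of -0.78, for example Cyp4p2 at -1.72, against Cyp6a8 at 3.02. Lipogenic genes had a median of -0.47, with 6 of 21 lower, among them the transcription factor sug at -1.60 and mino at -1.16. Lipolysis and fatty acid oxidation genes had a median of -0.39, autophagy genes -0.40, led by Atg9 at -1.77, and amylases, maltases and glycosidases -0.55. The marker lists of proventriculus and crop and of middle midgut and copper cell were low as well, at -0.46 and -0.35. Against the mean of the other 2 sucrose libraries, a reference chosen after seeing the data, the median of autophagy at 2 h was -0.25, inside the random range. The lipase gene bmm stood at -0.99 and Atg1 at -0.42, while FASN1, fatty acid synthase, stood at 0.70. The largest protein-coding differences belonged to other genes. Eggshell genes were far higher in the infected library, with Cp18 at 8.88, Cp19 at 7.12, Cp16 at 6.49 and Cp15 at 5.84, along with CG13083 at 6.05, and Femcoat was listed at the lowest value of the sucrose library and at 6.59 after infection. CG34324 was 158-fold lower and the mucin gene Muc68D 99.2-fold lower at 2 h, followed by CG34220 at -6.50, CG10725 at -5.94, CG3906 at -5.38, CG14645 at -4.98, Npc2c at -4.34, and by Mco4, while Dso2 and to were listed at 0 after infection. At 4 h the 8 of these genes other than Dso2 and to lay between -1.78 and -0.47. All of these except Npc2c are among 13 genes at least 8-fold lower in the 2 h infected library than in each other library. Over those 13 the 4 h sucrose library stood above the 2 h sucrose library by a median of 1.07. The 4 h differences therefore rest in part on that sucrose library. The genes CG16826, whe, CG34212 and lcs were higher by 7.25, 6.66, 6.20 and 5.67. Against the other 2 sucrose libraries CG16826 at 2 h stood at 3.81, lcs at 2 h at 2.74 and Npc2c at 2 h at -1.83.

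Cell cycle and DNA replication genes were higher at 2 h, with 18 of 29 at least 2-fold higher, 0 lower and a median of 1.16; CycB stood at 2.80, CycA at 2.52 and polo at 2.34. The ovary and eggshell marker list moved with them, with 15 of 18 genes higher and a median of 2.13, the highest of the 41 list medians at 2 h. Of the 41 lists, 8 were high and 11 low among random lists at 2 h.

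At 4 h genes of antibacterial and oxidative defence were higher, and the glycosidase, P450, fat metabolism and glycolysis lists were low. DptA was 53.8-fold higher, and DptB 23.8-fold, AttD stood at 4.64, and the glutathione transferase gene GstD2 was 22.8-fold higher. CG8745 was 32.0-fold lower. Hsp70Aa and Hsp70Ab, heat-inducible chaperones, stood at 4.58 and 4.73 after differences of 0.74 and 0.85 at 2 h. Altogether 644 genes were at least 2-fold higher and 674 lower, 559 and 643 of them protein-coding, with 33 of 63 rRNA genes higher and 0 lower, and 5 lists were high and 17 low. Against the mean of the other 2 sucrose libraries 11 lists were high and 10 low.

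Antimicrobial peptide genes had a median of 1.36 at 4 h, with 9 of 16 higher and 2 lower, and peptidoglycan recognition genes 0.65, with 5 of 14 higher and PGRP-SD at 4.21. The JAK-STAT median was 0.22, inside the random range, while upd3 stood at 3.69, Socs36E at 2.54 and upd2 at 1.38. Redox genes had a median of 0.57, with 14 of 37 higher and 3 lower, led by GstD5 at 5.84, GstD2 at 4.51, GstD8 at 4.41 and GstD6 at 3.83. Heat shock genes had a median of 0.86, with 10 of 21 higher and 1 lower. Members of the integrated and ER stress list were led by Sil1 at 2.69 and Gp93 at 2.26, with a list median of 0.25 inside the random range. CG13947 stood at 4.52 and CG8620 at 4.43. In contrast, Toll pathway and effector genes had a median of -0.53, with 6 of 18 lower and 0 higher, led by the bomanin genes BomS1 at -2.15 and BomS3 at -1.99, which encode Toll-dependent host defence peptides.

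Amylases, maltases and glycosidases had a median of -0.88 at 4 h, with 9 of 22 lower and 1 higher, including Mal-A7 at -2.31 and tobi, a glucosidase gene, at -2.26. The other digestive list, trypsin-like and Jonah proteases, had a median of -0.09 inside the random range, with 2 of 31 higher and 1 lower. P450 genes had a median of -0.65, with 16 of 37 lower; Cyp6a18 stood at -3.16 and Cyp6d2 at 4.10. Lipogenic genes had a median of -0.60, led by ACC at -1.64, lipolysis genes -0.44, led by the lipase-like CG6277 at -2.03, and autophagy genes -0.35, led by Atg9 at -1.78. Glycolysis and pentose phosphate genes had a median of -0.44, led by the trehalose synthesis gene Tps1 at -1.88. Duox and mol stood at -0.80 and -0.95, lower like the ovary and eggshell list, which had a median of -1.05. Whether ovary tissue carried over accounts for the 2 and 4 h values of these genes was not tested. Several lists of neighbouring tissues were low at the same time: Malpighian tubule at -1.40, fat body at -1.06, middle midgut and copper cell at -0.82, haemocyte at -0.70 and visceral muscle at -0.68. The median differences of the 4 h from the 2 h sucrose library were 0.54, 1.51, 0.10, 0.82 and 0.08 for these lists in the same order, and 0.31 for the Toll list. Against the other 2 sucrose libraries the median of fat body at 4 h was -0.21 and the median of Toll pathway and effectors at 4 h -0.19, both inside the random range, as was the median of lipogenesis at 4 h with -0.27, and the median of Malpighian tubule at 4 h was -0.98. The serine protease gene Ser8 stood at -3.40, the mucin gene Mur18B at -3.48, CG9259 at -3.90 and CG10514 at -3.52. The photoreceptor genes ninaE, Arr2 and Arr1 stood at -4.58, -3.80 and -3.65; their values in the 4 h sucrose library, 6.76, 5.38 and 5.20, exceeded those of 0.05, 0.34 and 0.02 in the 2 h sucrose library. Against the other 2 sucrose libraries ninaE at 4 h stood at 0.12, Arr2 at 4 h at -0.25 and Arr1 at 4 h at 0.05.

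Cell cycle genes had a median of -0.56 at 4 h, with 6 of 29 lower and 1 higher, RnrL, a ribonucleotide reductase subunit, at 2.32. The ovary and eggshell list had a median of -1.05, with the ovary-expressed genes dhd and Pxt at -3.88 and -3.62. Against the mean of the other 2 sucrose libraries dhd at 4 h stood at 0.04 and Pxt at 4 h at 0.09, and both medians turned positive, to 0.24 and 0.19, as did those of the haemocyte list, 0.33, and the proventriculus and crop list, 0.02.

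**Figure D1:**
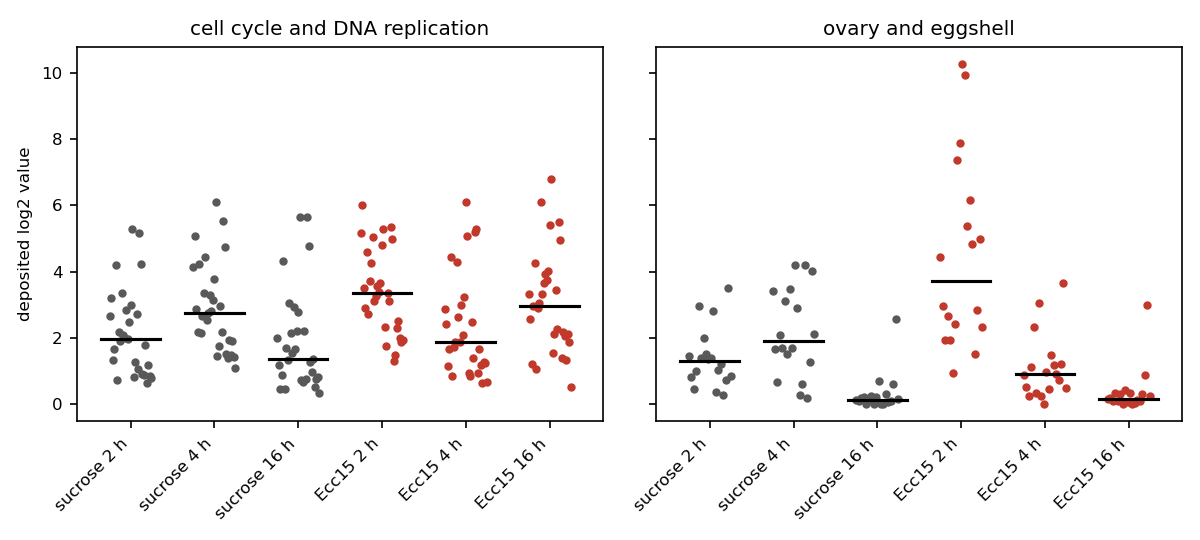
Deposited log2 value (vertical axis) of each measured member of the cell cycle and DNA replication list (left, 29 genes) and the ovary and eggshell list (right, 18 genes) in the 6 libraries, with bars at the list medians. The cell cycle medians are 1.96, 2.76 and 1.37 in sucrose and 3.34, 1.88 and 2.95 after Ecc15 at 2, 4 and 16 h, and the ovary medians 1.29, 1.90 and 0.14 against 3.70, 0.91 and 0.18.

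At 16 h genes of antibacterial defence, of the gut lining and of cell division were higher, and the antimicrobial peptide list had its largest median difference of the 3 times. AttD was 278-fold higher, DptA 94.0-fold, DptB 30.9-fold and PGRP-SD 29.4-fold. Against the other 2 sucrose libraries AttD at 16 h stood at 5.57 in place of 8.12, and GstD8 at 16 h at 4.83 in place of 6.67. Sucrose values at 2, 4 and 16 h were 3.73, 3.41 and 1.02 for AttD, and those at 4 and 16 h were 6.24 and 4.53 for GstD8. The antimicrobial list had median levels of 4.02, 3.29 and 3.69 after infection at 2, 4 and 16 h and of 2.11, 2.12 and 1.08 in sucrose, and the recognition list 6.34, 6.37 and 6.16 against 5.83, 5.78 and 5.04. GstD8 was 102-fold higher. The lipase-like gene CG6277 was 32.2-fold lower and Vha100-4, a proton pump subunit of copper cells, 18.0-fold lower, while another proton pump gene, Vha55, stood at -0.52. In total 629 genes were at least 2-fold higher and 621 lower, 527 and 579 of them protein-coding, with 19 of 63 rRNA genes higher and 3 lower, and 10 lists were high and 16 low, against 5 and 17 with the mean of the other 2 sucrose libraries as reference. The antimicrobial, recognition, heat shock, mucin and cell cycle lists were high with both references.

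Antimicrobial peptide genes had a median of 1.77 at 16 h, with 10 of 16 higher and 1 lower. Peptidoglycan recognition genes had a median of 1.32, with 8 of 14 higher, including PGRP-SC1a at 3.08 and PGRP-SC1b at 2.69, amidase genes. In sucrose PGRP-SC1a stood at 7.32, 7.45 and 4.89 and PGRP-SC1b at 8.29, 8.19 and 6.16 at 2, 4 and 16 h, and after infection they stood at 7.97 and 8.85 at 16 h. Peritrophic matrix and mucin genes had a median of 0.75, with 9 of 21 higher and 1 lower, led by CG32302 at 4.12 and the chitinase gene Cht4 at 3.57. Trypsin-like and Jonah proteases had a median of 0.48, with 6 of 31 higher and 2 lower, led by deltaTry at 2.20; against the mean of the other 2 sucrose libraries the median was -0.06. In sucrose CG32302 stood at 6.28, 5.71 and 3.54 and deltaTry at 11.02, 11.18 and 9.19 at 2, 4 and 16 h. The junction list, with 2 of 12 higher, had a median of 0.44; Gli and mesh, septate junction genes, stood at 1.06 and 1.01. The JNK list had a median of 0.46, and heat shock genes 0.75, led by Hsp23 at 2.29. Against the other 2 sucrose libraries the median of JNK pathway and targets at 16 h was 0.15, the median of cell junctions of the gut epithelium at 16 h 0.24 and the median of testis and accessory gland at 16 h 0.74, all inside the random range. The lysozyme genes LysP and LysX stood at 4.83 and 4.11, in a list with a median of -0.20 inside the random range. Redox genes had a median of 0.22, with 11 of 37 higher and 5 lower, which was -0.11 against the other 2 sucrose libraries. The genes CG34212, CG16826, whe, CG33109, lcs and CG13947 stood at 9.66, 8.30, 7.98, 5.98, 5.38 and 5.20. Their 4 h differences were smaller, from 2.72 to 4.52, with raised values in the 4 h sucrose library, such as 7.11 for CG16826 against 1.11 and 1.99 in sucrose at 2 and 16 h.

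Lower at 16 h were 17 of 37 P450 genes, with 1 higher and a median of -0.74, led by Cyp6a2 at -3.17. Lipogenic genes had a median of -0.55, with sug at -2.38 and Dgat2, a triglyceride synthesis gene, at -2.09, and lipolysis genes had a median of -0.44. The insulin and fasting list had a median of -0.57, with 8 of 17 lower and 2 higher; its members foxo, a transcription factor restrained by insulin, and daw, an activin ligand, stood at -2.06 and -2.02. AMPK, Hippo and TOR genes had a median of -0.40, with 7 of 25 lower and 0 higher. Amylases had a median of -0.36, with 6 of 22 lower and 4 higher, which was 0.08 against the other 2 sucrose libraries. The metallothionein gene MtnC stood at -2.56 in a metal list with a median of -0.39, and the clock gene tim at -1.36 in a circadian list with -0.48. Toll genes had a median of -0.46, led by BomS3 at -1.65. CG15263, CG1946, Cpr49Ae and the carotenoid receptor gene ninaD stood at -5.15, -3.45, -3.97 and -3.48, CG15021 at -3.42 and Dso2 at -4.77, and CG42680 was listed at the lowest value of the library in the 5 libraries other than 16 h sucrose. Muscle, haemocyte, copper cell, Malpighian tubule and fat body lists had medians of -0.68, -0.78, -0.62, -0.47 and -0.46. Against the other 2 sucrose libraries the median of circadian clock at 16 h was -0.07, the median of Malpighian tubule at 16 h -0.18 and the median of intestinal stem cell and progenitor at 16 h -0.25, all inside the random range, while ninaD at 16 h stood at -0.56 and CG15263 at 16 h at -1.16. Those sucrose libraries are of other times, so for clock genes above all this reference mixes infection with time.

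Cell cycle genes were higher again at 16 h, with 18 of 29 at least 2-fold higher, 0 lower and a median of 1.21; PCNA, the replication clamp, stood at 3.07, RnrL at 2.64, Mcm5 at 2.10 and CycE at 2.08. The ovary and eggshell median was 0.06 at that time, with 0 of 18 genes past 2-fold, and the stem cell and progenitor list stood at -0.39, with mira at -2.67 and Delta, the Notch ligand of stem cells, at 1.32.

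**Figure D2:**
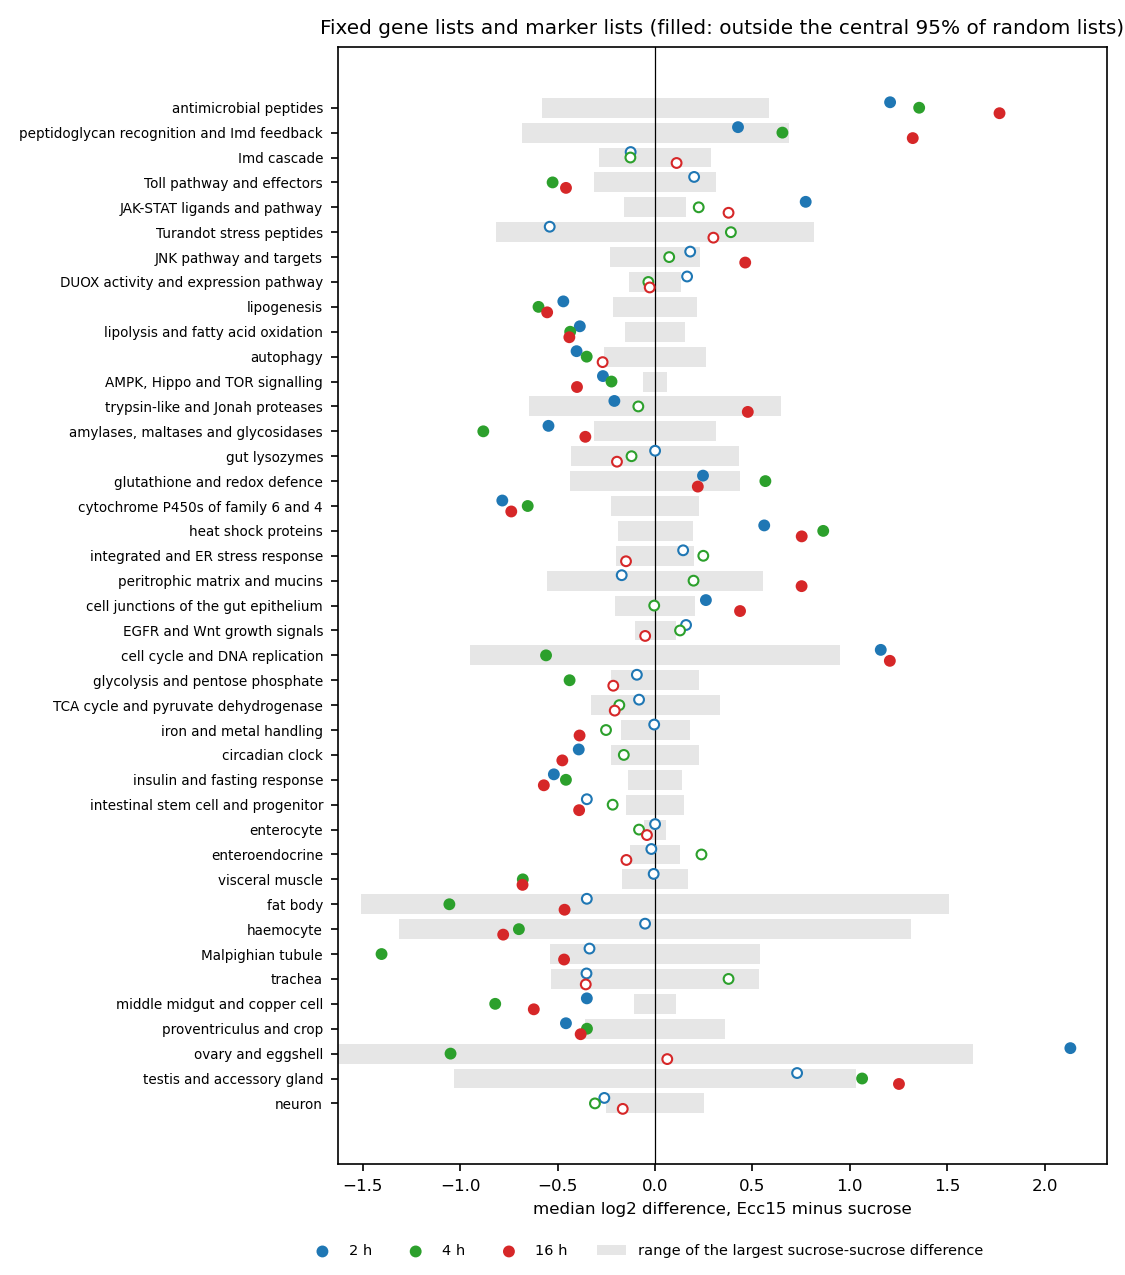
Median log2 difference, Ecc15 minus sucrose of the same time (horizontal axis), for the 41 lists at 2, 4 and 16 h, filled where the median lies outside the central 95% of random lists, with grey bars spanning the largest difference between sucrose libraries in either direction. Antimicrobial peptide medians are 1.21, 1.36 and 1.77 and P450 medians -0.78, -0.65 and -0.74, whereas the cell cycle medians are 1.16, -0.56 and 1.21.

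The sustained comparison asked which genes differed at all 3 times. At least 2-fold higher at 2, 4 and 16 h were 127 genes, with 2.75 expected from independent lists, and 128 were lower, with 2.48 expected. Of these, 122 and 122 lay wholly outside the range of the 3 sucrose libraries. The 2-fold rule at every time already favours this, so it is not separate support. The immune genes AttD, DptA, PGRP-SD, CecA1 and upd3 were among the 10 leading higher genes, with whe, CG16826, CG13947 and CG33109 and the small RNA gene snoRNA:Psi18S-525a. The 10 leading lower genes were CG8745, Dso2, CG2061, RluA-1, Acsf2, CG13796, mlt, GstT4, CG10621 and atos. GstT4, a glutathione transferase gene, stood at -1.94, -2.66 and -1.92 at 2, 4 and 16 h. Of the genes higher at 2 h, 218 were also higher at 4 h (40.2 expected) and 199 at 16 h (39.2 expected), and 230 were higher at both 4 and 16 h (44.1 expected). The corresponding lower counts were 247 (36.6 expected), 172 (33.7 expected) and 254 (45.6 expected). In opposite directions, 61 genes higher at 2 h were lower at 4 h and 8 were lower at 16 h. Of the genes higher at 4 h, 6 were lower at 16 h. For genes lower at the earlier and higher at the later time these counts were 5, 20 and 23. Across genes, which are not independent replicates, the differences had Spearman correlations of 0.51 between 2 and 4 h, 0.49 between 2 and 16 h and 0.53 between 4 and 16 h.

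Averaged over the times, limma called 4 of 14 genes of peptidoglycan recognition and Imd feedback that rose, and 5 of 25 AMPK, Hippo and TOR genes, 4 of 22 autophagy genes and 9 of 37 P450 genes that fell. The Imd inhibitor pirk rose by 2.93 ± 0.15 (SE, log2, 3 libraries per treatment; limma with Benjamini-Hochberg adjustment, adjusted p = 0.027), and upd3 rose by 3.47 ± 0.20 (limma, adjusted p = 0.027). The hormone subunit gene Burs rose by 2.33 ± 0.14, the serpin gene Spn42Da by 2.19 ± 0.13, and CG42335, CG42362, CG4563, CG34198 and CG13947 by 2.12, 2.17, 1.95, 1.84 and 4.53. REPTOR-BP, the partner of a TOR-regulated transcription factor, changed by -1.78 ± 0.11 (limma, adjusted p = 0.027), and CG2061 changed by -2.93 ± 0.12. RluA-1, Acsf2, CG13796, mlt, CG32486, Cyp12a5, the Bcl-2 family gene Buffy and CG13255 changed by -2.44, -2.12, -2.24, -1.98, -1.84, -1.51, -1.79 and -1.65. With Socs36E these are the 10 genes per direction with the smallest limma p, and each differed in the same direction in 3 of 3 pairs. Limma with Benjamini-Hochberg adjustment called 170 genes that rose and 267 that fell, and 2497 genes had an unadjusted p under 0.05. These counts depended on the fit: limma called 0 and 0 genes without the intensity trend (2419 unadjusted), 0 and 0 without a filter on low values (2789 unadjusted), 0 and 0 without the 2 h or without the 16 h libraries (1728 and 1919 unadjusted), and 1 and 1 without the 4 h libraries (1472 unadjusted). Infected and sucrose values did not overlap for 1229 higher and 1641 lower genes, 31.3% together, where chance gives 10% for a single gene. Genes that move together within a library are not independent, and this share was not computed for other splits, so it is not a test.

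By list, 4 of 16 antimicrobial peptide genes rose over all genes tested and 8 adjusted over the list alone: DptA by 5.46 ± 0.50, DptB by 4.05, CecA1 by 3.98 and CecA2 by 2.77 passed in both (the size for CecA1 is uncertain, as it was listed at the lowest value in the 2 h sucrose library), while AttD, at 5.52, missed the threshold (limma, adjusted p = 0.0501). In the recognition and feedback list 4 rose, pirk, PGRP-SD by 4.20, PGRP-LF by 2.19 and PGRP-LB by 1.94, and adjusted over the list alone 6 rose and 1 fell. In the JAK-STAT list upd3, Socs36E by 2.66 and the receptor gene dome by 1.03 rose, and 4 rose adjusted over the list alone. In the JNK list Ets21C by 3.02 and Gadd45 by 2.70 rose and the ligand gene egr changed by -0.78, with 4 and 4 adjusted over the list alone. Hsp83 and stv, both by 0.97, rose among heat shock genes (5 adjusted over the list alone), RnrL by 2.26 among cell cycle genes (1 adjusted over the list alone), and CG6429 by 2.48 among lysozymes (1 adjusted over the list alone). GstD2 rose by 3.46 ± 0.39 while GstE9 and maf-S changed by -1.03 and -1.11 in the redox list, with 12 up and 4 down adjusted over the list alone.

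Among metabolic lists, 5 of 21 lipogenic genes fell: the desaturase gene Desat1 and AcCoAS, Lpin, bigmax and Lsd-2 changed by -0.87, -0.83, -0.80, -1.18 and -0.86, and adjusted over the list alone 11 fell and 1 rose. ACC stood at -1.26 (limma, adjusted p = 0.0501), and FASN1 at 0.07 with adjusted p = 0.897 by limma. Of 28 genes of lipolysis and fatty acid oxidation, whd and Acox57D-p changed by -1.67 and -1.17 and CG4860 rose by 0.92, with 14 down and 2 up adjusted over the list alone. All 3 AMPK subunit genes fell, AMPKalpha with -0.87 ± 0.12 (limma, adjusted p = 0.0424), alc with -1.03 and SNF4Agamma with -0.79, together with Rheb, an activator of TOR, with -0.99, and REPTOR-BP; 8 of the 25 fell adjusted over the list alone. Atg9, Atg101 and Pi3K59F, which act in autophagosome formation, changed by -1.52, -1.30 and -1.17, and Atg2 fell as well, with 10 down and 3 up adjusted over the list alone. Of 37 P450 genes 9 fell, for example Cyp6a2 with -2.52 and Cyp4ac1 with -1.80 (14 down and 1 up adjusted over the list alone). In the glycosidase list tobi, LManI, Gal and Hexo1 changed by -1.75, -1.44, -1.30 and -0.94 (6 down and 1 up adjusted over the list alone). In the insulin and fasting list ImpL2, an insulin-binding protein gene, rose by 1.19, and chico and tobi changed by -0.86 and -1.75 (2 up and 6 down adjusted over the list alone). MFS14 fell in the circadian list by 1.01 (0 up and 2 down adjusted over the list alone). The averaged difference had a median of -0.48 for lipogenesis, -0.49 for lipolysis and -0.33 for autophagy. Among marker lists it was -0.78 for fat body and -0.70 for both Malpighian tubule and middle midgut, but -0.03 for enterocyte, 0.02 for enteroendocrine and 0.55 for ovary. A change in the tissue held by the libraries was not tested apart from infection for these lists.

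Limma with adjustment over all genes called 0 genes in 12 further pathway lists. Without adjustment, limma gave p under 0.05 for 2497 of 9183 genes, a share to hold beside the unadjusted counts of each list. The adjustment over a list alone makes no allowance for the 41 lists examined. Up and down at an unadjusted p under 0.05 were 4 and 2 Imd cascade genes (3 and 2 adjusted over the list alone), 4 and 3 ER stress genes (4 and 1), 5 and 0 junction genes (3 and 0), 1 and 5 Toll genes, 2 and 0 DUOX genes, 2 and 4 proteases, 5 and 3 mucins and 5 and 3 EGFR and Wnt genes, with 0 adjusted over the list alone in the last 5. Also at 0 by limma over all genes and adjusted over the list alone were glycolysis (3 and 8 unadjusted), TCA cycle (0 and 2), metal (0 and 4) and Turandot genes (0 and 0). Medians at 2, 4 and 16 h were 0.16, -0.03 and -0.03 for the DUOX list, 0.16, 0.13 and -0.05 for EGFR and Wnt, -0.08, -0.18 and -0.21 for the TCA cycle and -0.54, 0.39 and 0.30 for Turandot peptides, each inside the random range. Duox, mol, wts and Traf-like had limma adjusted p of 0.88, 0.706, 0.981 and 0.499, and bmm and Atg1 0.109 and 0.126. AttA, an attacin gene, never reached an FPKM-scale value of 1 and so was not analysed. How reads of related genes were split is unknown, so this does not show that AttA was not expressed.

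**Figure D3:**
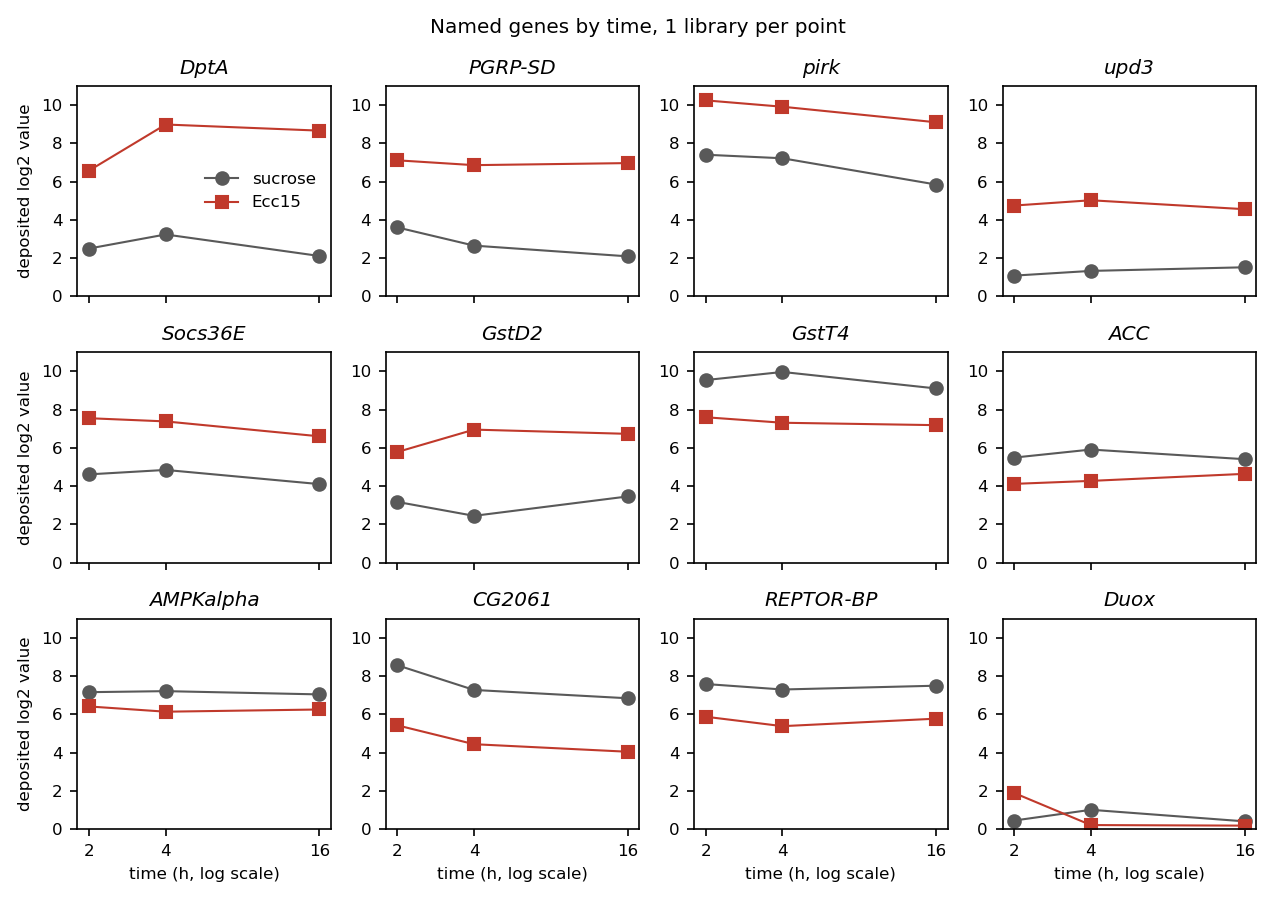
Deposited log2 values (vertical axes) of 12 genes against time in h (horizontal axes, log scale) in sucrose (grey circles) and Ecc15 (red squares), with 1 library per point and no error bars. DptA lies 4.07, 5.75 and 6.55 higher after Ecc15 at 2, 4 and 16 h, CG2061 differs by -3.14, -2.84 and -2.80, and Duox by 1.44, -0.80 and -0.22.

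Marker lists of other cell types were measured to describe what each dissection held. Limma over all genes called dve and Ptx1, transcription factors of the middle midgut, with -0.77 and -0.85, in the copper cell list (2 adjusted over the list alone), dve again in the proventriculus and crop list (1 up and 2 down adjusted over the list alone), and CG15406 with -1.23 in the Malpighian tubule list (2 down adjusted over the list alone). It called 0 genes in the other 10 marker lists. The unadjusted counts that follow stand beside 2497 of 9183 over all genes. Unadjusted p was under 0.05 for 2 up and 5 down among stem cell and progenitor genes (1 and 2 adjusted over the list alone) and for 2 up and 0 down among 3 testis and accessory gland genes (2 and 0 adjusted over the list alone). For enterocyte, enteroendocrine, muscle, fat body, haemocyte, trachea, ovary and neuron genes it was under 0.05 for 1 and 2, 1 and 0, 0 and 7, 0 and 4, 0 and 4, 0 and 0, 0 and 0, and 0 and 1, with 0 adjusted over the list alone. Enterocyte medians were 0.00, -0.08 and -0.04 at 2, 4 and 16 h and enteroendocrine medians -0.02, 0.24 and -0.15. Trachea medians were -0.35, 0.38 and -0.36 and neuron medians -0.26, -0.31 and -0.17. All these medians lay inside the random range. The enterocyte list holds some of the highest values, such as alphaTry at 13.05 in all 3 sucrose libraries and the 2 h infected library. Forcing libraries to the same distribution can pin such values, so enterocyte medians near 0 do not show an unchanged share of enterocytes. Proventriculus and crop medians were -0.46, -0.35 and -0.38, and testis and accessory gland medians 0.73, 1.06 and 1.25.

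Change over time in sucrose was compared with change over time after infection. Among protein-coding genes, ninaE, CG15263, Cpr49Ae and CG15213 were higher and CG17475, dhd, Npc2c, Mal-B1 and CG31789 lower at 16 h than at 2 h in sucrose. CG31789 stood at 8.33 and 4.04 log2 in sucrose at these times and at 8.04 and 8.51 after infection. After infection the largest negative differences of 16 h to 2 h among protein-coding genes were those of the eggshell genes Cp18, Cp19, Cp16, Cp15 and Femcoat, with Cp18 at -9.92, and the largest positive ones among protein-coding genes those of CG34324, Muc68D, CG34220, CG10725 and to. The small RNA gene snoRNA:Me18S-A1061 stood at 11.14 in the 2 h infected library and was listed at 0 at 16 h. In sucrose, 297 genes were at least 2-fold higher and 153 lower at 4 h than at 2 h, and 228 higher and 287 lower at 16 h than at 2 h. After infection the counts were 355 and 398 for 4 h and 486 and 628 for 16 h. Both 16 h counts use the 2 h libraries, and without them 142 genes were higher and 349 lower at 16 h than at 4 h in sucrose, and 378 and 424 after infection.

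Small RNA genes took most of the largest differences at single times. Of the 10 largest, genes that are not protein-coding held 9 higher and 8 lower places at 2 h, 8 and 10 at 4 h, and 6 and 10 at 16 h. Examples listed at the lowest value of 1 library of a pair were snoRNA:Or-CD8, at 10.64 after infection at 2 h and 11.03 at 16 h, mir-79, at 15.41 in the 4 h sucrose library, and mir-9c, at 14.82 in the 16 h sucrose library. At 2 h snoRNA:Me28S-A2564 stood at 13.88 in sucrose and 1.18 after infection. The microRNA genes mir-2a-1 and mir-2a-2 both stood at 15.11 in the 4 h infected library alone and at 0.53 or less elsewhere. The rRNA genes counted above are near-identical copies of 1 gene, the 5S rRNA gene, so they are not separate observations. Between sucrose libraries 0 of the 63 were higher and 0 lower at 4 h than at 2 h, and 3 were higher and 0 lower at 16 h than at 2 h. Of 19 snRNA genes, 9 were higher and 0 lower after infection at 2 h, 4 and 4 at 4 h, and 12 and 3 at 16 h, against 7 and 3 in sucrose at 16 h compared with 2 h. Such short RNAs lack poly(A) tails for the most part, and their values in poly(A) libraries are uncertain. Coordinates of genes that recur above, as given in the table whose build is not stated, are 2R 14753270 to 14753765 for DptA (FBgn0004240), 2R 17548472 to 17549749 for pirk (FBgn0034647), X 18171266 to 18178632 for upd3 (FBgn0053542), 3L 7644305 to 7645000 for PGRP-SD (FBgn0035806), X 10986526 to 10988697 for CG2061 (FBgn0027498), 2L 10264131 to 10265229 for REPTOR-BP (FBgn0032202), X 1269580 to 1272890 for AMPKalpha (FBgn0023169) and 2L 2815970 to 2830236 for Duox (FBgn0283531).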

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

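All tests in this part were chosen after the results had been seen. The differences between times given here were not tested, since each time has 1 library per treatment.

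The cell cycle list was high at 2 and 16 h and low at 4 h, with medians that differed by 1.72 between 2 and 4 h and by 1.77 between 16 and 4 h, and the ovary and eggshell list differed by 3.18 between 2 and 4 h. The eggshell genes Cp18, Cp19, Cp15 and Cp16 and the ovary-expressed genes Pxt and dhd went the same way, with log2 differences between the 2 and 4 h effects of 12.1, 9.56, 9.07, 8.19, 6.43 and 6.15; Cp16 was listed at 0 in the 4 h infected library, so its value is uncertain. Ovary tissue carried over at 16 h is argued against as the source of the higher cell cycle genes there, since the ovary median was 0.062 at that time while the cell cycle median was 1.21. At 2 h it may contribute: in the 4 h sucrose library, where the ovary list stood 1.09 above the other sucrose libraries, the cell cycle list stood 0.79 above them without infection. An effect of infection on the cell cycle genes stays open and was not tested apart from this at 2 h, and at 4 h both directions rest on that sucrose library.

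Picked from these values, 7 genes (CG13947, CG16826, CG34212, LysP, CG33109, lcs and whe) were at least 4-fold higher than in the 2 and 16 h sucrose libraries both after infection and in the 4 h sucrose library. Admixture of an infected library is argued against: as the excess over the mean of the 2 and 16 h sucrose libraries, these genes reached a median of 11.7% of their infected 4 h excess (3.54 to 38.6%), while 7 immune genes reached 0.884% (-1.79 to 4.18%). The immune genes were chosen in 3 ways. The 7 above were at least 4-fold higher in the infected 4 h library than in the 2 and 16 h sucrose libraries. The other 2 ways gave 0.150% with 14 genes and 0.884% with 21. The 14 were at least 2-fold higher after infection at 4 h, a rule that uses the 4 h sucrose library and so favours a low share. The 21 were at least 2-fold higher at 2 or 16 h, and some may not be raised at 4 h. Head or eye tissue remains open, since 15 of 21 photoreceptor genes were 2-fold higher in the 4 h than the 2 h sucrose library, and the 16 h sucrose library, the other sucrose library with raised photoreceptor transcripts, held 1.34% of the 4 h excess of the 7 genes against 19.8% for photoreceptor genes, which is a single library. No biological explanation was tested.

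The 13 protein-coding genes at least 8-fold lower in the 2 h infected library than in each of the other 5 included CG34324, Muc68D and CG34220. A part of the gut missing from that dissection may account for them, and so may an early effect of infection. The genes also moved together between libraries that held them. Their median was 1.07 between the 4 and 2 h sucrose libraries (percentile 100 of random lists, central range -0.19 to 0.16). It was 0.73 between the 16 and 4 h infected libraries (percentile 99.99). Genes regulated together could move so under either account, so these values do not separate them. If a part was missing, which part is open: the proventriculus and crop list stood at -0.46 at 2 h, with 3 members above 0 and 9 below. An early effect of infection was not tested apart from a missing part.

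The protease median differed by 0.69 between 16 and 2 h, low at 2 h and high at 16 h, but against the mean of the other 2 sucrose libraries it turned to 0.12 at 2 h and -0.062 at 16 h. Between the 16 and 2 h sucrose libraries this list had a median difference of -0.65. The 16 and 4 h effects of CG9259 differed by 5.34.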

How the results depend on the processing

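The alternatives using the mean of the other 2 sucrose libraries, protein-coding genes alone, 16 h against 4 h and the sustained response with a time left out were chosen after seeing the data. The limma fit paired the infected and sucrose libraries of each time, and without the time term it called 208 genes up and 321 down. Of the list medians under the alternatives, 646 moved by less than the sucrose-sucrose difference, 83 by more and 9 turned. Of named gene values these counts were 1848, 149 and 13. With the mean of the other 2 sucrose libraries alone, 83 list medians moved by less, 32 by more and 8 turned. Each list was held to its own sucrose-sucrose difference, so lists that varied in sucrose had a looser limit. With the mean of the 3 sucrose libraries as reference the median of trypsin-like and Jonah proteases at 2 h turned to 0.00704, snoRNA:Psi28S-2149 at 16 h to 2.65 and snRNA:U5:63BC at 16 h to -0.34, and 9 lists were high at 4 h and 6 at 16 h. Against the mean of the other 2 sucrose libraries, medians turned for proteases at 2 h (0.12) and 16 h (-0.062), amylases at 16 h (0.078), redox genes at 16 h (-0.11), and at 4 h for cell cycle (0.24), haemocyte (0.33), proventriculus and crop (0.021) and ovary genes (0.19), and 11 lists were high and 10 low at 4 h and 5 high at 16 h. Of named genes, that reference turned snoRNA:Me28S-A2564 at 2 h (0.27), snoRNA:Psi28S-3091b at 2 h (0.025), CG17475 at 2 h (0.50), Mco4 at 4 h (0.017), ninaE at 4 h (0.12), dhd at 4 h (0.044), Arr1 at 4 h (0.054), Pxt at 4 h (0.094), Mal-B1 at 4 h (-0.035), snoRNA:Psi28S-2149 at 16 h (5.04) and snRNA:U5:63BC at 16 h (-3.19). The small RNA genes named here are uncertain, since each was listed at the lowest value in at least 1 sucrose library. Limma called 0 genes up and 0 down without a filter (2789 unadjusted) and without trend (2419 unadjusted), and between 0 and 1 in each direction when a time was left out; fewer libraries leave fewer residual degrees of freedom. Limma's other settings called 118 to 249 genes up and 191 to 369 down. Sustained genes numbered 199 to 230 higher and 172 to 254 lower with a time left out, where fewer conditions must be met. With a pseudocount of 0.1, 786 genes were lower at 2 h and 939 at 16 h, and 200 were sustained higher. With a pseudocount of 5, higher and lower counts after infection were 314 and 242 at 2 h, 391 and 417 at 4 h and 384 and 374 at 16 h, and 82 were sustained lower. At 1.5-fold they were 1238 and 1296, 1371 and 1463, and 1329 and 1458, with 335 genes higher in the sustained infection response and 421 genes lower in the sustained infection response. At 3-fold they were 270 and 146, 261 and 260, and 291 and 209, with 53 and 22 sustained. Counts over time are given in the order genes higher in sucrose at 4 h than at 2 h, genes lower in sucrose at 4 h than at 2 h, genes higher in sucrose at 16 h than at 2 h, genes lower in sucrose at 16 h than at 2 h, genes higher in infected guts at 4 h than at 2 h, genes lower in infected guts at 4 h than at 2 h, genes higher in infected guts at 16 h than at 2 h and genes lower in infected guts at 16 h than at 2 h. They were 125, 57, 112, 144, 171, 201, 238 and 351 with a pseudocount of 5, 629, 529, 776, 831, 976, 884, 1271 and 1337 at 1.5-fold, and 105, 52, 98, 105, 124, 181, 203 and 280 at 3-fold. With a pseudocount of 0.1 the first 5 were 505, 342, 411, 493 and 614 and the seventh 742. Beyond the range of the 3 sucrose libraries lay 358 and 258 genes at 2 h, 387 and 253 at 4 h and 322 and 323 at 16 h. In sucrose, 142 genes were higher at 16 h than at 4 h. Dropping the filter changed no 2-fold count, since it removes no gene that could reach 2-fold. Apart from these constructions the cause was not tested. Depth is unknown, so it sets no stated limit. For the 437 genes called by limma, 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 437 and the highest of the others 10. That is not a comparison with chance, since many of the others put both libraries of a time in 1 group. With the time term kept, such a split rests on the infected and sucrose pair of a single time. The other splits that divided the pair of every time called 0 genes.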

Other observations

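Several leading genes of the infection response lie beside each other in the table's coordinates, a feature picked out after their values were seen. On 3R, CG42335 (17584496 to 17595023) and Burs (17595273 to 17595916) rose by 2.12 and 2.33 (limma). On 2R, DptA (14753270 to 14753765) and DptB (14754895 to 14755400) rose by 5.46 and 4.05, and pirk (17548472 to 17549749) and CG42362 (17551938 to 17553613) by 2.93 and 2.17. On X, lcs (21267754 to 21268326) and whe (21273400 to 21273765) rose by 4.62 and 6.04. Whether reads were shared between such neighbours was not tested, and enrichment of neighbours over chance was not tested.

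The tests in this part were chosen after the values had been seen. Of the 405 entries left out for missing or repeated identifiers, 120 had an FPKM-scale value of at least 5 in some library; 0 were at least 2-fold higher and 3 at least 2-fold lower at all 3 times.

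Photoreceptor genes, listed after ninaE had been seen, had median differences of 0.21, -1.42 and -0.54 at 2, 4 and 16 h over 21 genes. No explanation beyond the one above was tested for them.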
